A study of Mus musculus with 16 samples.

How the data were processed

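Single-cell RNA sequencing was analysed from 16 libraries in 13 groups, all mouse. Per the labels, 8 libraries formed a time course of the KPC model of pancreatic ductal adenocarcinoma: tumours on days 10, 20 and 30, healthy pancreas, blood drawn on the same days and blood of healthy mice. Another pair of libraries came from day 7 tumours titled wild type (WT) and COX2-KO. Each of these 10 libraries pooled 3 female mice and was the only library of its group. A pair of libraries came from genetically engineered mice with autochthonous KPC tumours (GEMM), 1 male and 1 female. The remaining 4 came from male mice inoculated with a KC cell line, in the pancreas (orthotopic, 2 libraries) or elsewhere (heterotopic, 2 libraries), collected on day 33 and sorted for CD45 and CD11b, markers of leukocytes and of myeloid cells. The KC libraries used an earlier version of the 10x Genomics 3' kit than all other libraries. Tumours and pancreas were dissociated with an enzyme kit and red blood cells were lysed. The labels do not say whether the 2 KC libraries of a group came from different mice, so p-values for them measure only the spread between these libraries, which may be technical. Nor do the sources used here say whether the tumour cells or the host of the COX2-KO library lacked Ptgs2, the gene of COX2, or which part of it was removed, and the genotype entry of that library reads WT while its title names the knockout.

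The deposited files hold UMI counts (unique molecular identifiers, 1 per captured transcript) per gene and barcode, whole numbers with no normalisation. Per the submitters' processing notes they were made with Cell Ranger 4.0.0 on the mouse build mm10, which aligns reads, counts UMIs and keeps barcodes called as cells. The file headers of the time course name Cell Ranger 6.0.1 and list 32285 genes; those of the day 7 and GEMM libraries name 3.0.2 and list 27998 genes; the KC files name no version and list 27998 genes. Values were therefore compared within each of 5 sets alone (pancreas and tumour time course, blood time course, day 7, GEMM, KC), except tumour against blood, which share 1 gene table, and GEMM values, some of which are set beside those of healthy pancreas without a test. How free RNA was treated upstream is not given in the sources used here, and no correction for it was applied. Gene coordinates were taken from the GENCODE M21 annotation of mm10.

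Barcodes with at least 500 UMIs, at least 250 genes and under 15% mitochondrial UMIs were kept as cells. The mitochondrial limit removed 5493 of 21348 barcodes on day 20, 4875 of 11388 in healthy pancreas and 4587 of 9140 in the second GEMM library, and from 1 to 3725 in each other library. In blood, 5711 to 10678 barcodes per library fell under the gene minimum, and 5573 to 10393 of them drew more UMIs from haemoglobin than from all other genes. Doublets were called per library with Scrublet through scanpy 1.11.5 and removed. Where it marked under 0.5% of over 5000 barcodes (tumour days 10 and 20, healthy pancreas, first GEMM library), the top-scored barcodes were removed instead, at 0.8% per 1000 barcodes and at most 10%. In the day 7 pair 368 barcodes (3.88%) were removed from WT but 13 (0.378%) from COX2-KO. Cells kept numbered 13983, 14261 and 17109 in the tumours of days 10, 20 and 30, 5813 in healthy pancreas, 12066, 13768 and 15996 in blood of days 10, 20 and 30, 12763 in healthy blood, 9119 (WT) and 3426 (COX2-KO) on day 7, 8169 and 4526 in the GEMM libraries, 574 and 1937 in the orthotopic and 682 and 918 in the heterotopic KC libraries.

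Each set was clustered alone with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 on a graph of 15 nearest neighbours over 30 principal components of 2000 variable genes. Clusters were named from 20 marker lists fixed before the data were examined, with "-like" added to each name. A name needed at least 3 markers detected in 15% of the cluster's cells at 2 times the reference level or more, and a cluster was left unnamed where another list held more of its top 10 genes, or where its cells had few UMIs and none of the name's markers led it. The scoring was revised after clusters had been seen: the reference is now the lower of all sets together and the cluster's own set, and either alone is given as an alternative. This named 96.9% of cells in the pancreas set, 93.5% in blood, 75.4% on day 7, 96.2% in GEMM and 80.9% in KC. The unnamed day 7 clusters held 22.6% of WT and 29.9% of COX2-KO cells, and those of the KC set 10.6% and 32.9% of the orthotopic and 4.69% and 6.10% of the heterotopic cells. No pancreas cluster was named monocyte-like, so tumour monocytes were not compared with blood, and healthy pancreas had 14 neutrophil-like cells, under the minimum of 20 for a class.

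Counts were summed per library and class. With 1 library per group there is no replicate check: counts scaled to the same total per class (CPM) were compared as log2 ratios with exact conditional 95% intervals, levels carry exact Poisson and shares exact Clopper-Pearson intervals, and all of these cover counting error only. Where 1 library had no UMI, the ratio is a bound against a floor of 3 UMIs in that library's class, and the same floor over the group served in the tests. Lists were summarised by the median log2 ratio of members with at least 20 UMIs, given with its percentile among 10000 random lists of the same size matched on mean expression. In these comparisons "above" and "below" count members by the sign of the ratio, leaving out bounds that do not exclude no change. The share of cells with an Il1b UMI was measured after thinning each cell to 1500 UMIs and leaving out shallower cells. Co-detection is the log2 odds ratio, with 0.5 added to each cell count, between having a UMI of Il1b and of another gene in thinned macrophage-like cells of a library.

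Replicated comparisons used edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM given as mean ± SD use the TMM-scaled totals and so differ from the class CPM of single libraries. Orthotopic KC libraries were compared with heterotopic ones in macrophage-like and neutrophil-like cells; monocyte-like and dendritic-like cells had under 20 cells in a library and were not tested. The 3 tumour libraries were compared with the 3 blood libraries of the same days in neutrophil-like cells with day as a term. The libraries are pools of mice on different days, so the spread is that between days. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, with fry as a further alternative; DESeq2 1.42.0 was the other gene test. A gene was called above the rest where its CPM in the neutrophil-like cells of the higher tissue exceeded that of all other cells in each library of that tissue, a criterion added after the data were seen. Shares of KC cells were compared with an exact two-sided permutation test.

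The 21 state lists, the marker lists, the tests, the class comparisons and the rule for named genes were fixed before the data were examined. The rule names (a) 11 focal genes, (b) in tested comparisons the 10 genes with the largest log2 fold change in each direction among those past the threshold that differ the same way in every pair of libraries, and in single-library comparisons the 8 with the largest log2 ratio in each direction among those with at least 100 UMIs and 50 CPM in the higher library and an interval that excludes no change, and (c) up to 4 members of each described list with the largest change. Under (b), unnamed gene models, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes and markers of other classes were passed over; the last are given as groups. Where neighbouring names stand out for another reason, the text says that they were chosen after their values were seen. A few genes that the rule names are not reported here.

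Statistics were tested on simulated data with 200 changed genes or known rates. For KC macrophage-like cells (7330 genes), edgeR recovered 0%, 55.2% and 86.4% of genes changed 2-, 4- and 8-fold, with 6.93% false calls. KC neutrophil-like cells (3900 genes) gave 0%, 16.4% and 77.3%, with 10.1% false calls, and tumour against blood (9955 genes) 43.3%, 88.1% and 98.5%, with 7.83%. At its preset correlation camera called the 2-fold raised list in all 3 simulations and none of 20 unchanged ones. At an estimated one it missed the raised list in each (adjusted p = 0.827, 0.989 and 0.568, Benjamini-Hochberg). Real list members may vary together more, so this favours neither setting. Ratio intervals held the true value for 95.5% of 9808 genes and binomial intervals in 96.8% of draws. Of 200 unchanged lists, 7.5% lay above percentile 95.

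Alternatives were stricter cell filters (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, resolutions 0.5 and 2, median ratio scaling, thinning to 1000 or 3000 UMIs, DESeq2 or its size factors, no low-count filter, each library or day left out, no day term and the replicate number as a block; the other naming references, fry and calls above the rest were chosen after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.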

Results

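Single cells of mouse pancreatic tumours, healthy pancreas and blood were profiled in 16 droplet-based 3' libraries. According to its title the study concerned tumour macrophages that express Il1b. The KPC tumours of days 10, 20 and 30 gave 116084040, 135174008 and 161305970 UMIs and healthy pancreas 49473620, with 1 library each. Blood of the same days gave 85273296, 91304813 and 79432262 UMIs and healthy blood 90010516. The day 7 tumours labelled WT and COX2-KO gave 67793145 and 31980599 UMIs, and the GEMM libraries 70954463 and 47718992. The KC libraries were the shallowest, with 1791295 and 11071923 UMIs for the orthotopic pair and 3247192 and 6672781 for the heterotopic pair. The median kept cell had between 1582.5 UMIs in the first orthotopic KC library and 6214 in the first GEMM library.

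The genes followed throughout are all protein-coding and are placed here on mm10. Il1b (ENSMUSG00000027398), the gene of the cytokine interleukin-1 beta, lies on chromosome 2 from 129364570 to 129371139, close to Il1a (ENSMUSG00000027399; 129299610 to 129309972), which encodes interleukin-1 alpha. Il1rn (ENSMUSG00000026981), which encodes the antagonist of their receptor, lies on chromosome 2 from 24336853 to 24351494. Ptgs2 (ENSMUSG00000032487), the gene of the prostaglandin-forming enzyme COX2, lies on chromosome 1 from 150100031 to 150108227, and Ptges (ENSMUSG00000050737), the gene of a prostaglandin E synthase, on chromosome 2 from 30889471 to 30929863. Tnf (ENSMUSG00000024401), the gene of tumour necrosis factor, lies on chromosome 17 from 35199381 to 35202007. Nlrp3 (ENSMUSG00000032691), the gene of an inflammasome sensor, lies on chromosome 11 from 59541568 to 59566956. Cxcl2 (ENSMUSG00000058427), the gene of a neutrophil-attracting chemokine, spans 90903871 to 90905938 on chromosome 5, and Spp1 (ENSMUSG00000029304), the gene of osteopontin, spans 104435118 to 104441050 there. C1qa (ENSMUSG00000036887), which encodes a chain of complement C1q, lies on chromosome 4 from 136895917 to 136898803, and Folr2 (ENSMUSG00000032725), which encodes a folate receptor of resident macrophages, on chromosome 7 from 101839988 to 101857194.

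The time course compares healthy pancreas with tumours of increasing age. Macrophage-like cells made up 3.03% of healthy pancreas cells (95% interval 2.60 to 3.50) and 33.4% (32.6 to 34.2), 12.5% (11.9 to 13.04) and 23.3% (22.7 to 24.0) of tumour cells on days 10, 20 and 30. Neutrophil-like cells made up 0.241%, 21.2% (20.5 to 21.9), 4.84% and 13.1% (12.6 to 13.6) in that order. T cell-like cells held 44.4% (43.1 to 45.7) of healthy pancreas and 14.1%, 2.32% and 4.41% of the tumours, and B cell-like cells 33.8% and at most 8.27%. Clusters with Lef1 and Tcf7 or Fcer2a and Cr2 among their top genes held 1301, 1195 and 1860 healthy cells but at most 51 of a tumour. A difference in tissue sampled was not tested. Epithelial-like cells, which include the tumour cells, held 3.63% on day 10, 49.2% (48.4 to 50.1) on day 20 and 31.1% (30.5 to 31.8) on day 30, and fibroblast-like cells 2.89%, 15.2% and 7.75%. A cluster led by osteoclast genes and left unnamed held 0.286%, 2.09% and 5.21% of tumour cells on days 10, 20 and 30. With 1 pool of mice per group these shares have no replicate check, and each depends on the others and on survival of dissociation. The day 10 macrophage-like share was 21.8% with classes named within the set.

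**Figure D1:**
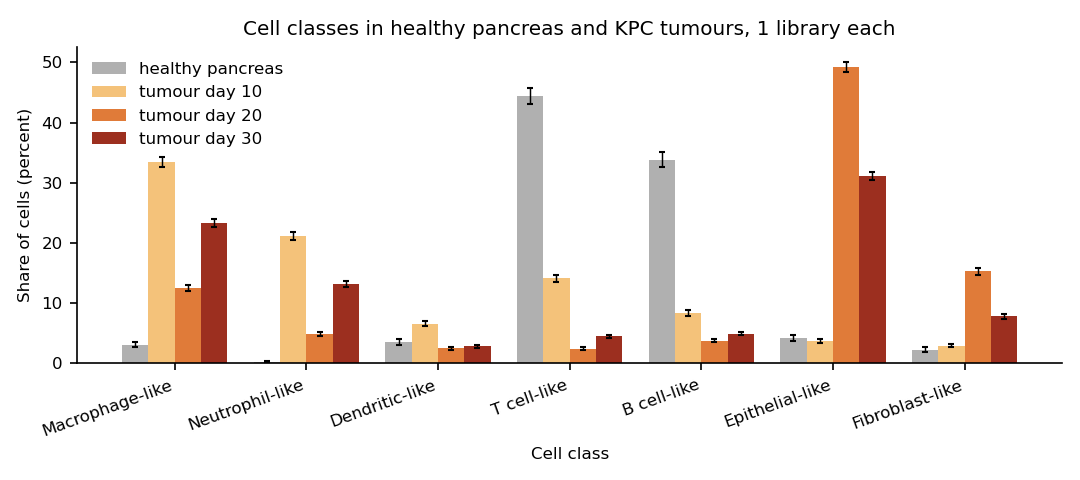
Share of cells (percent of kept cells, y axis from 0) of 7 cell classes (x axis) in healthy pancreas and in KPC tumours of days 10, 20 and 30, with 1 library per bar and exact 95% binomial intervals that cover counting error only. Macrophage-like cells went from 3.03% of healthy pancreas to 33.4% on day 10, and epithelial-like cells reached 49.2% on day 20.

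Macrophage-like cells of the day 30 tumour carried far more transcripts of inflammatory mediators than those of healthy pancreas. Of the 176 healthy cells, 91 came from a shallow cluster led by the acinar genes Pla2g1b and Clps, which held 14 of the 3992 day 30 cells. Its median cell had 0.258 times the median UMIs of its library, so the healthy levels are no clean macrophage baseline. Il1b stood at 5574 CPM against 93.3, a log2 ratio of 5.90 (95% interval 5.59 to 6.23), Il1a at 385 against 4.50 (6.42, 5.06 to 8.29) and Il1rn at 1232 against 23.6 (5.71, 5.09 to 6.40). Ptgs2 stood at 2048 CPM against 2.25, the latter from 2 UMIs (9.83, 7.98 to 12.88). Tnf (6.59, 5.37 to 8.21), Cxcl2 (6.82, 6.35 to 7.32), Nlrp3 (4.77, 4.15 to 5.48) and Spp1 (7.19, 6.35 to 8.20) were higher as well. Ptges had 126 UMIs on day 30 and none in healthy pancreas, which makes it at least 1.75-fold higher. C1qa was close in both, at 3162 and 2492 CPM (0.34, 0.28 to 0.41), and Folr2 was lower, at 40.3 against 288 CPM (-2.84, -3.04 to -2.63).

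Beyond these genes, Arg1, the gene of arginase 1 (9.91, 8.06 to 12.95, from 2 UMIs in healthy pancreas), Vegfa, a growth factor of blood vessels (8.93, 6.45 to 14.23, 1 UMI), the cytokine gene Il6 (8.09, 5.61 to 13.39, 1 UMI) and Nr4a3, an orphan nuclear receptor (8.04, 5.56 to 13.35, 1 UMI), were among the genes with the largest ratios. Cxcl1, another neutrophil-attracting chemokine, was at least 282-fold higher. The lowest ratios were those of the acinar enzyme genes Ctrl (-6.05), Sycn (-5.66), Spink1 (-5.05), Cela1 (-5.00) and Pla2g1b (-4.99) and of Rnase1 (-5.82), with the lysozyme gene Lyz1 at -5.84 and Retnla, a gene of alternatively activated macrophages, at -5.64 (-5.75 to -5.54). All 10 acinar markers were lower in the day 30 macrophage-like cells (median -5.32), and 10 of 10 T cell markers too (-4.15), while neutrophil (9 of 10, 3.29), epithelial (7 of 10, 2.80) and fibroblast markers (8 of 10, 2.17) were mostly higher.

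By group, all 15 measured inflammatory cytokine genes were above the healthy level on day 30 (median 5.90, percentile 100 among random lists), led by Ptgs2, Cxcl1, Cxcl2 and Tnf. All 12 Spp1 and hypoxia genes were above it (4.41, percentile 100), with Arg1, Vegfa, Spp1 and the lipid droplet gene Hilpda (6.07) in front. Of 17 genes that respond to TNF or IL-1, 15 were above and 2 undecided at this depth (3.82, percentile 100), among them the acute phase gene Saa3 (5.24). The IL-1 system list had 7 of 11 genes above (0.95, percentile 99.3), with Il1r2, the gene of a decoy receptor, at 6.00. Resident macrophage genes went the other way, with 10 of 12 below (-1.57, percentile 0): Timd4, a receptor for dying cells, stood at -5.64 (-6.27 to -5.04), the hyaluronan receptor gene Lyve1 at -4.40 (-4.62 to -4.18) and the haemoglobin scavenger receptor gene Cd163 at -4.32 (-4.67 to -3.97). MHC class II genes were below for 7 of 8 (-0.68, percentile 5.48), with their regulator Ciita at -1.47. The interferon response list was split, 6 above and 7 below (-0.26, percentile 14.7). The prostaglandin pathway list had 6 genes above and 3 below of 10 (0.37, percentile 87.5), with the degrading enzyme Hpgd at -4.69 (-5.12 to -4.26). Dissociation stress genes were above in 12 of 12 (1.27, percentile 99.8), proliferation genes in 10 of 12 (1.29, percentile 100) and neutrophil granule genes in 8 of 10 (1.17, percentile 99.8).

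**Figure D2:**
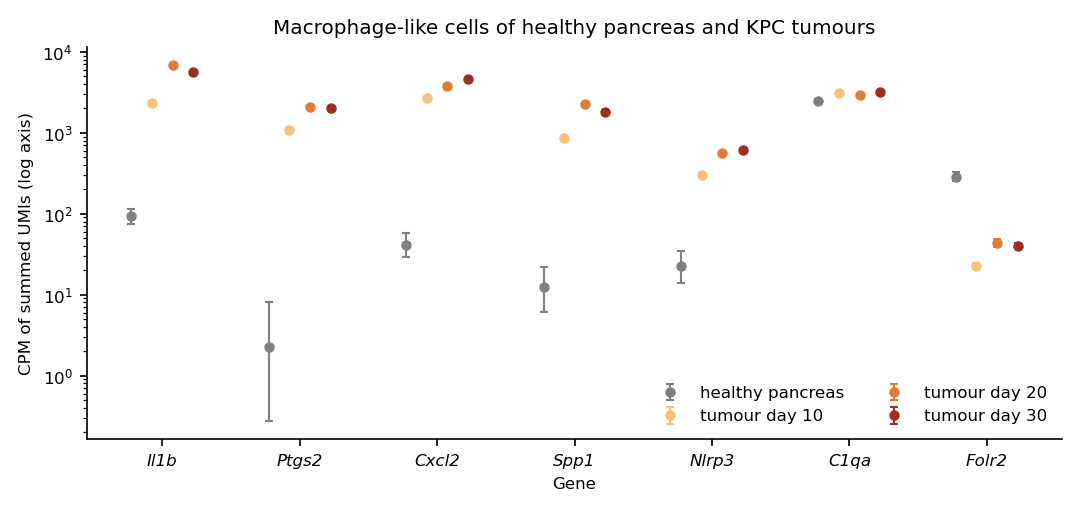
Level in macrophage-like cells (CPM of summed UMIs, log axis) of 7 genes (x axis) in healthy pancreas and in KPC tumours of days 10, 20 and 30, 1 library per point, with exact 95% Poisson intervals that cover counting error only. Il1b lay at 93.3 CPM in healthy pancreas and at 2353, 6867 and 5574 CPM in the tumours, C1qa between 2492 and 3162 CPM in all 4 libraries, and Folr2 below its healthy level of 288 CPM in each tumour.

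Much of this difference was already present on day 10, when Il1b stood at 2353 CPM (log2 ratio to healthy pancreas 4.66, 4.35 to 4.98), Ptgs2 at 1074 (8.90, 7.05 to 11.95) and Spp1 at 867 (6.13, 5.29 to 7.13). Arg1 (10.23, 8.37 to 13.27) had the largest ratio, while Lyve1 (-6.86), Cd163 (-6.50) and Pla2g2d, a secreted phospholipase gene (-6.29), had the lowest and Folr2 stood at -3.65 (-3.86 to -3.44). All 15 cytokine genes (median 3.86) and all 12 Spp1 and hypoxia genes (4.09) were above the healthy level and 8 of 12 resident macrophage genes below it (-1.17). Unlike on day 30, interferon response genes were mostly above, 9 of 13 (0.67, percentile 99.6), with the interferon-induced chemokine gene Cxcl9 at 3.39 (3.11 to 3.69), the guanylate-binding protein gene Gbp2 at 3.08 and Cxcl10 at 2.45, and MHC class II genes in 7 of 8 (0.35, percentile 93.2). On day 20 the cytokine list median was 5.74, that of the Spp1 and hypoxia list 4.45 and that of the resident macrophage list -1.90. Acinar markers were lower than in healthy macrophage-like cells on all 3 days, with medians of -2.10, -6.34 and -5.32.

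Set directly against day 10, day 30 macrophage-like cells were higher in Il1b (1.24, 1.23 to 1.26), Ptgs2 (0.93, 0.91 to 0.95), Tnf (1.09), Nlrp3 (1.03), Spp1 (1.06), Il1a (0.91), Cxcl2 (0.82), Il1rn (0.66) and Folr2 (0.81, 0.67 to 0.96), with C1qa at 0.01 (-0.01 to 0.02) and Ptges at -0.29 (-0.61 to 0.02). Plet1 (4.05), Adamdec1 (3.59), the chemokine gene Cxcl3 (3.35), the IL-23 subunit gene Il23a (3.21) and Ifitm1 (3.19) had the highest ratios. The chemokine gene Ccl5 (-5.29), Ly6i (-4.43), the cytotoxic granule gene Nkg7 (-4.21), Slamf7 (-4.19) and Gbp2b (-3.95) were lowest. Cytokine genes were higher on day 30 in 14 of 15 cases (1.03, percentile 100), with Ereg, a growth factor gene, at 3.39 and Osm, the oncostatin M gene, at 1.71. Proliferation genes were higher in 12 of 12 (0.65, percentile 100), for example Ccnb2 at 1.10 and Ccnb1 at 0.97. MHC class II genes were lower in 8 of 8 (-1.11, percentile 0), with H2-Eb1 at -1.59 and Ciita at -1.54, and interferon response genes in 12 of 13 (-0.70, percentile 0), with Cxcl9 at -3.66 (-3.72 to -3.59) and Gbp2 at -2.36. Resident macrophage genes were split evenly (-0.14, percentile 18.2). T cell markers were lower in 10 of 10 cases (-3.51), as were cytotoxicity genes in 8 of 8 (-3.73). The libraries drew on different clusters: 2833 of the 4673 day 10 cells came from 1 cluster and 1629 from another, whereas 2154 and 1717 of the 3992 day 30 cells came from a further pair. The cluster with 1629 day 10 cells was the shallow one led by acinar genes, with 91 of the 176 healthy cells.

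After each cell had been thinned to 1500 UMIs, Il1b was detected in 6.43% of healthy macrophage-like cells (2.98 to 11.9), 75.3% on day 10 (73.8 to 76.8), 94.8% on day 20 (93.5 to 95.8) and 91.9% on day 30 (90.9 to 92.7). Without thinning the shares were 14.8%, 82.8%, 96.9% and 95.4%, and thinning left out 36, 1389, 231 and 235 shallower cells. The thinned healthy share was 15.3% with classes named within the set. T cell-like cells, taken as the background of free RNA, had Il1b in 0.0779% of healthy, 14.4% of day 10, 15.7% of day 20 and 26.5% of day 30 cells, at median depths of 5312.5, 4422, 1113 and 1388 UMIs against 3819.5, 5445, 3235 and 4635.5 in macrophage-like cells. In summed counts, macrophage-like cells held 63.0% of the Il1b UMIs of the day 30 library and 51.3% of its Ptgs2 UMIs, and neutrophil-like cells 22.5% and 20.04%.

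Within macrophage-like cells of single libraries, the median log2 odds ratio with Il1b was positive for most genes of the cytokine list and negative for most resident genes. Over 10 tissue libraries with enough cells, Ptgs2 (median log2 odds ratio 2.20, range 0.69 to 3.23), Il1a (1.58, 0.50 to 2.56) and Vegfa (1.21, 0.21 to 3.86) had positive values in all 10. Nlrp3 (1.61), Tnf (0.90) and Osm (0.97) did in 9, whereas Ereg of the same list had negative values in 7 (-1.08, -6.28 to 2.56). A gene with no UMI in a library still gets a value, whose sign follows from the share of cells with Il1b alone. That value is 2.56 in the second GEMM library, where 25 of 175 cells had Il1b. In the first orthotopic KC library, where 194 of 196 had it, the value is -6.28. The upper end for Il1a and both ends for Ereg are such values, which say nothing about co-detection. The complement gene C1qb (-1.10), Folr2 (-1.69), the selenium carrier gene Selenop (-0.76), Gas6, a ligand of receptors for dying cells (-1.65), and the lipid transfer gene Pltp (-1.22) had negative values in all 10, and C1qa (-0.89) and Lyve1 (-2.08) in 9. Since nearly all cells of the first orthotopic KC library had Il1b, a rarely detected gene is negative there by construction. The lowest value of Folr2 and Lyve1, -4.69, is that of a gene found there in a single cell, which also had Il1b. Spp1 was positive in only 3 (-0.17), although the Spp1 and hypoxia list had a positive median (0.38 over 12 genes), against 0.94 for the cytokine and -1.16 for the resident macrophage list. The number of genes positive or negative in every library takes in such libraries. It moved with the processing, from 1 to 7 of 14 cytokine genes (2 here) and from 1 to 9 of 12 resident genes (5 here), over 8 to 10 libraries.

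**Figure D3:**
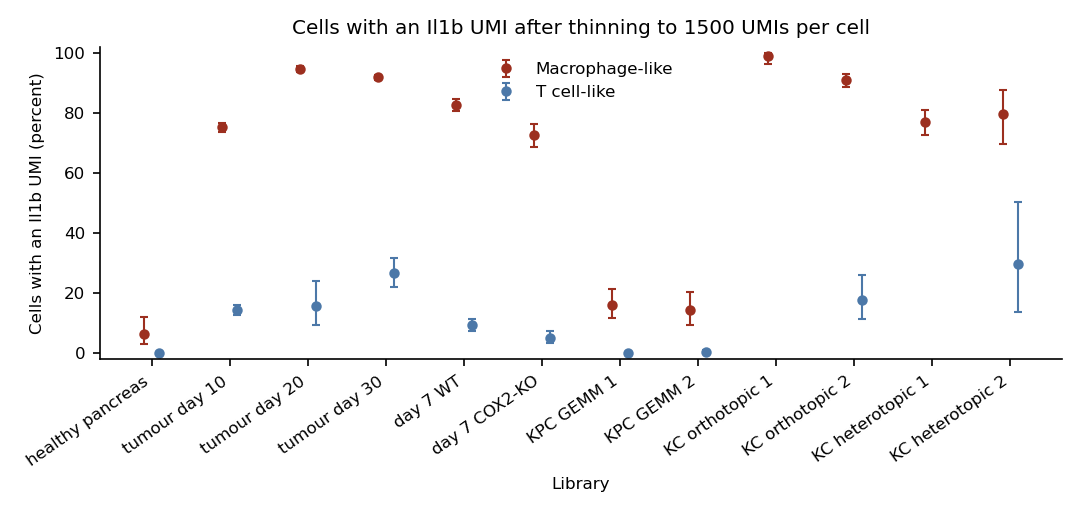
Share of cells with at least 1 Il1b UMI (percent, y axis) after thinning to 1500 UMIs per cell, in macrophage-like (red) and T cell-like (blue) cells of each tissue library (x axis), with exact 95% binomial intervals that cover counting error only. In the time course, macrophage-like cells ranged from 6.43% in healthy pancreas to 94.8% on day 20. T cell-like cells, taken as background, reached 26.5% on day 30. Macrophage-like cells of the first orthotopic KC library stood at 98.98%.

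Neutrophil-like cells were compared between tumours alone, since healthy pancreas had too few. Il1b was already at 12319 CPM on day 10 and stood at 16108 on day 30 (0.39, 0.37 to 0.40), with Ptgs2 at 3436 and 6479.8 CPM (0.92, 0.89 to 0.94), Spp1 at 1.19 and Nlrp3 at 0.27, whereas Tnf did not differ beyond counting error (-0.02, -0.08 to 0.04). Il1a (-0.41) and Il1rn (-0.12) were lower, and Cxcl2 was among the most abundant transcripts in both, at 17803 and 20249 CPM (0.19). C1qa (0.53), Folr2 (1.39, 0.05 to 2.76) and Ptges (1.30) were higher. Il33 (4.83), F2r (4.71), Cpe (4.55), Mmp13 (4.44) and Cdh17 (4.33) had the highest ratios. F2r and Mmp13 are top genes of an epithelial-like cluster with 5 day 10 and 1313 day 30 cells, and Cpe of another with 13 and 1516. Free RNA was not tested for them. The acinar genes Prss3 (-7.19, -12.50 to -4.70, 1 UMI on day 30), Cela1 (-4.85) and Ctrl (-4.47) and the interferon-induced genes Gbp4 (-5.18), Cxcl9 (-4.53) and Igtp (-3.79) had the lowest. Interferon response genes were lower on day 30 in 12 of 13 cases (-2.19, percentile 0), with Gbp2 at -3.49, and MHC class II genes in 7 of 8 (-0.80). Neutrophil granule genes were higher in 7 of 10 (1.86, percentile 100), including Ngp (2.61), Camp (2.01) and Ly6g (2.61). The same held for 11 of 12 Spp1 and hypoxia genes (0.76, percentile 100), 15 of 17 TNF and IL-1 response genes (0.75, percentile 100) and 9 of 14 cytokine genes (0.33, percentile 98.0), with Cxcl3 between 3.90 and 4.11 by its interval, Ccl4 at -1.58 and Osm at 1.41. Tissue neutrophil genes were split, 6 and 6 (-0.15). Epithelial markers were higher on day 30 (8 of 9, median 2.04), fibroblast markers too (10 of 10, 0.74), and acinar markers lower (10 of 10, -3.32). With classes named within the set the cytokine list turned to -0.03, Cxcl2 to -0.17 and Nlrp3 to -0.09. A cluster held 2908 of the 2960 day 10 cells, another 2218 of the 2241 day 30 cells.

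Fibroblast-like cells of the day 30 tumour had higher levels of myofibroblast genes than those of healthy pancreas. Tagln, the gene of transgelin, stood at a log2 ratio of 8.94 (7.40 to 11.22, from 3 UMIs in healthy pancreas), Acta2, the gene of smooth muscle actin, at 6.54 (5.77 to 7.45) and the myofibroblast marker gene Lrrc15 at 5.67 (3.81 to 8.72, 2 UMIs). The myofibroblast list was above the healthy level in 9 of 10 genes (median 4.04, percentile 100), with Tnc at 4.96. Of the inflammatory fibroblast list 7 of 10 genes were above (2.07, percentile 100), with Il6 at 7.48 (5.00 to 12.79, 1 UMI), Cxcl1 at 5.11, the hyaluronan synthase gene Has1 at 4.28 and Clec3b at -6.15 (-6.27 to -6.02). The TNF and IL-1 response list had 14 of 17 above (2.43, percentile 100), led by Cxcl2 (8.65, 6.18 to 13.96, 1 UMI) and Saa3 (8.29, 7.31 to 9.50). The plasminogen activator inhibitor gene Serpinb2 (8.27), Chl1 (7.61), Ccn4 (7.60) and the haptoglobin gene Hp (6.91) followed, each from 1 UMI in healthy pancreas. The lowest ratios were those of Efhd1 (-10.70, 2 UMIs on day 30), Tek (-8.68), Opcml (-8.46), Krtdap (-8.25) and Dact2 (-7.84). Ptgs2 stood at 307 against 30.6 CPM (3.33, 2.85 to 3.85), Ptges at 83.2 against 51.7 (0.69, 0.31 to 1.09), and Il1r1, the gene of the signalling IL-1 receptor, at 2.74 (2.25 to 3.28). The prostaglandin pathway list had 8 of 12 genes above (0.55, percentile 96.9), among them the receptor genes Ptger3 (3.83) and Ptger2 (2.10). Il1b was at 179 CPM in these cells and at 351 CPM in T cell-like cells of the same library, and neutrophil markers were higher in them than in healthy fibroblast-like cells (median 2.44). All 12 Spp1 and hypoxia (1.96), proliferation (1.85) and dissociation stress genes (2.07) were above, while acinar markers were below (-4.51). Of the 129 healthy cells 91 came from a cluster that held 270 of the 1326 day 30 cells, and another held 945 of them.

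Neutrophil-like cells of tumours were compared with those of blood to ask what distinguishes them in tissue. Il1b rose from 2872 ± 295 CPM in blood to 13557 ± 3617 in tumours (TMM-scaled, SD, n = 3 each; log2 fold change 2.21, SE 0.256, adjusted p = 3.99e-05, edgeR with Benjamini-Hochberg adjustment). Larger rises were seen for Cxcl2, from 14.6 ± 5.30 to 16475 ± 1825 CPM (10.16, SE 0.385, adjusted p = 4.83e-08), Il1a (11.53, SE 0.401), Ptgs2, from 28.9 ± 17.8 to 4538 ± 1505 CPM (7.43, SE 0.486), and Tnf, from 9.77 ± 3.17 to 1156 ± 240.2 CPM (6.95, SE 0.296). Il1rn (4.04, SE 0.235) and Nlrp3 (2.99, SE 0.208) rose too. Each of these 7 genes was also above the rest of the cells in every tumour library, unlike Spp1 (7.97, SE 0.311), C1qa (9.13, SE 0.359) and Ptges (5.47, SE 0.688, 3 UMIs in blood), which in tumours stood at 0.390, 0.140 and 0.241 times the level of other cells. In all, 3500 of 10180 genes rose and 2953 fell. Only 708 of the former and 1657 of the latter were above the rest of the cells of the tissue in which they were higher.

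Among the largest rises by the naming rule were those of the orphan receptor genes Nr4a3 (12.48) and Nr4a2 (12.02), Cxcl1 (12.35), Tm4sf4 (at least 593-fold), Cxcl3 (11.69), the metallothionein gene Mt2 (at least 673-fold), the matrix metalloproteinase gene Mmp14 (at least 655-fold) and Reg1 (11.20), a gene of acinar cells. Nr4a3, Nr4a2, Cxcl1 and Reg1 had 1 UMI in blood, and the lower limits of their ratios of summed counts were 11.59, 11.87, 10.82 and 11.85. These limits cover counting error only, in sums that weigh libraries by their depth, and are no bounds on the fitted values, which depend on a prior count. The fitted 11.20 of Reg1, at 306 ± 437 CPM in tumours (SD, n = 3), lies below its limit. Among the largest falls were Gp1ba and Tubb1, genes of platelets, and Trim10, a gene of red cell precursors. Mpig6b (at least 110.9-fold), Gucy1b1 (at least 50.2-fold), Gp1ba (at least 48.3-fold), Lrrn3 (at least 46.7-fold), Trim10 (at least 38.6-fold), Ly6g6c (at least 38.5-fold), Tubb1 (at least 32.8-fold) and Ttll11 (at least 22.0-fold) had no UMI in tumours, and Nrgn (-8.82, SE 0.322) had 22 UMIs there. All 6 erythroid and all 7 platelet markers fell (medians -8.94 and -8.76, the latter -7.03 with genes at 0 put at their bound), and none was above the rest of the blood cells. All 10 acinar markers rose, as did 9 of 9 epithelial, 9 of 9 fibroblast and 9 of 10 macrophage markers, and none of these was above the rest of the tumour cells.

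By list, 14 of 14 inflammatory cytokine genes rose (median 7.19, camera adjusted p = 9.98e-29, Benjamini-Hochberg; adjusted p = 0.222 with an estimated correlation), and all 14 were above the rest. Of 12 tissue neutrophil genes 12 rose and 11 were above the rest (7.70), among them the chemokine gene Ccl3 (9.97, SE 0.424) and Hilpda (9.79). TNF and IL-1 response genes rose in 15 and fell in 1 of 16 cases (7.12, or 5.96 with 5 genes at 0 in blood put at their bound), 7 of the former above the rest, with Il6, not among them, at least 200.4-fold and the granulocyte growth factor gene Csf3 at least 167-fold higher. Spp1 and hypoxia genes rose in 10 of 12 and fell in 1 (3.12; Arg1 8.63, Vegfa 5.29), 5 of the former above the rest but not Arg1, and the IL-1 system list had 5 of 10 higher and 2 lower (1.12; Il1r2 2.63). Dissociation stress genes rose in 11 of 12, or 12 when adjusted over the list alone (2.98; Egr1 6.48, Hspa1a 5.88), 6 of them above the rest. Neutrophil granule genes fell in 7 of 10, or 8 when adjusted over the list alone (-3.93, adjusted p = 4.21e-06 by camera with Benjamini-Hochberg and 0.308 with an estimated correlation), with Camp at -5.19, the resistin-like gene Retnlg at -4.75, Ngp at -4.43 and Mmp8 at -4.36, although Camp stood at 2.86 and Ngp at 2.89 with classes named within the set. An unnamed tumour cluster led by Ltf and Ngp, closest to neutrophils, held 11, 123 and 195 cells on days 10, 20 and 30. The class left it out but kept a blood cluster led by Lcn2, Ltf and Ngp, with 3, 23 and 58 cells. Naming within the set adds the tumour cluster, so the falls of Camp and Ngp depend on leaving it out. Naive T cell genes fell in 5 of 7 (median -1.50), with 7 of 10 T cell markers lower as well. None of the members that rose was above the rest in the lists of resident macrophage (6 of 7 rose, 8.39, or 6.30 with a gene at its bound), epithelial (7 of 7, 7.36) and proliferation genes (9 of 11, 2.98), and 1 was among inflammatory fibroblast genes (7 of 8, 8.90, or 6.23 at bounds). Mesenchymal genes rose in 4 of 7 (0.92). Camera called these 13 lists with its preset correlation and none with an estimated one, at adjusted p between 0.222 and 0.505 (Benjamini-Hochberg).

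The other 8 lists were not called by camera. Interferon response genes were split, with 3 higher and 6 lower of 13 (-0.18; Cxcl10 4.91, Ifit3 -2.44). MHC class II genes rose in 6 of 8 (1.15; H2-DMb1 1.88, H2-Ab1 1.35), with H2-Ab1 at -0.68 when doublets were kept, and prostaglandin pathway genes in 6 of 8 with 1 lower (1.16; Ptgs1 1.29, the receptor gene Ptger2 -2.20). Monocyte identity genes rose in 3 and fell in 5 of 11 cases (-0.16; Hp -3.79, the thrombospondin gene Thbs1 3.02). T cell cytotoxicity genes rose in 3 of 5 (0.93; Gzmb 2.94), T cell checkpoint genes in 2 of 3 (4.63), regulatory T cell genes in 2 of 4 (2.22) and myofibroblast genes in 2 of 3 with Acta2 at -1.60 (2.88). When adjusted over each list alone, counts changed only for dissociation stress, granule and resident macrophage genes, the last with 1 more gene that fell. The labels describe enzymatic dissociation for tissue and lysis of red cells alone for blood, so tissue and handling cannot be told apart in this comparison, and the 3 libraries per tissue came from different days.

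**Figure D4:**
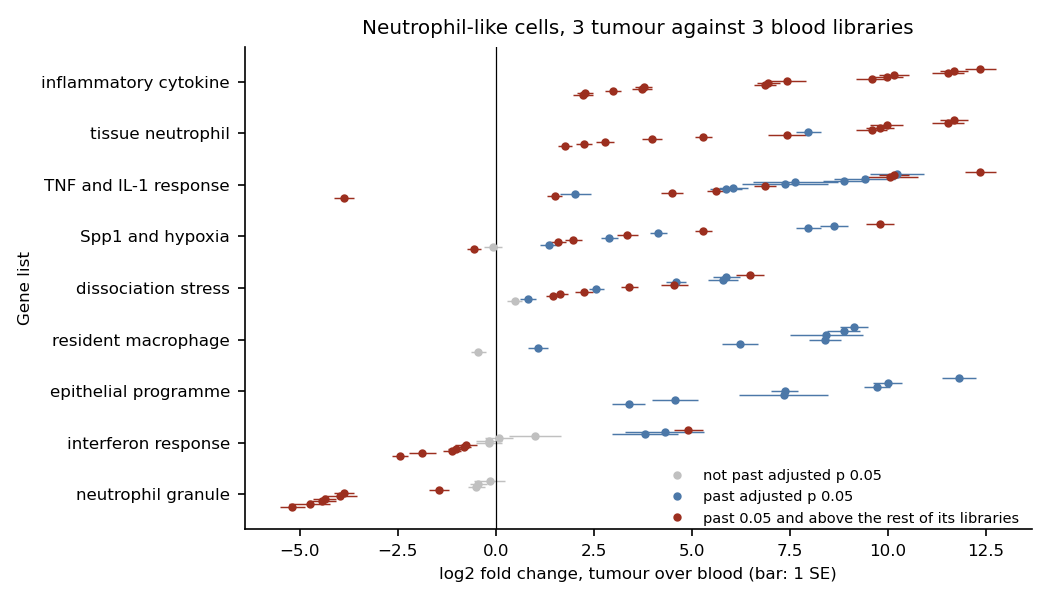
Log2 fold change in neutrophil-like cells between tumours and blood (x axis) for the members of fixed gene lists (y axis), from edgeR with 3 libraries per tissue and bars of 1 SE. Red points mark genes past an adjusted p of 0.05 (Benjamini-Hochberg) that were also above the rest of the cells of the tissue in which they were higher, which was so for 14 of 14 inflammatory cytokine genes and 0 of 7 resident macrophage genes.

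In blood, neutrophil-like cells made up 10.8% of cells in healthy mice (10.2 to 11.3) and 9.07%, 29.8% (29.0 to 30.5) and 39.1% (38.3 to 39.8) on days 10, 20 and 30. Monocyte-like cells made up 6.09%, 5.22%, 9.33% and 9.36% in the same order, and B cell-like cells 28.4%, 34.9%, 22.6% and 17.3%. Day 30 neutrophil-like cells of blood had Il1b near its healthy level, at 2258 against 2353 CPM (-0.06, -0.09 to -0.03), and 0.05 after median ratio scaling. Ptgs2 was lower, at 9.25 against 74.9 CPM (-3.02, -3.32 to -2.72), as were Cxcl2 (-1.73), Tnf (-1.06), Nlrp3 (-0.34), Il1rn (-0.33) and Spp1 (-1.06, -1.97 to -0.09). The protease inhibitor genes Stfa2 (5.80) and Cstdc5 (5.01), Eps8 (3.80) and Wfdc17 (3.78) had the highest ratios, and Itgb7 (-1.57), the immediate early gene Egr1 (-1.47) and the cystine transporter gene Slc7a11 (-1.43) low ones. Neutrophil granule genes were above the healthy level in 9 of 10 cases (1.32, percentile 100), for example Ngp at 1.80 and Ly6g at 1.61, and cytokine genes below it in 9 of 11 (-0.45, percentile 0.65). MHC class II genes were below in 8 of 8 (-1.10, percentile 0), as were 8 of 8 B cell markers (-1.61).

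Monocyte-like cells of day 30 blood had Il1b at 111 against 68.8 CPM (0.69, 0.54 to 0.85), Tnf at -2.03 (-2.50 to -1.56) and Nlrp3 at 0.13 (-0.12 to 0.38), while Ptgs2 had 0 and 4 UMIs on day 30 and in healthy blood. Wfdc21 (7.44), Saa3 (6.43), Lrg1 (6.27), Ifitm1 (4.57) and the siderophore-binding protein gene Lcn2 (4.40) had the highest ratios, Hpgd (-3.00), S1pr5 (-2.70) and Cd300e (-2.62) the lowest. Spp1 (5.85, 4.30 to 8.14, 3 UMIs in healthy blood) and C1qa (8.17, 5.68 to 13.47, 1 UMI) were higher. Granule genes were above in 8 of 9 cases (2.59, percentile 100), with the elastase gene Elane at 4.48, proliferation genes in 10 of 11 (1.31, percentile 100), with Stmn1 at 3.41, and monocyte identity genes in 10 of 11 (0.83, percentile 100), with Vcan at 2.96 and Chil3 at 2.59. Interferon response genes were below in 11 of 13 (-0.60, percentile 0.03), with Ifit3 at -1.94, Cxcl10 at -1.82 and Cxcl9 at 4.96, and the list median turned to 0.24, Ifit3 to 0.61, Cxcl10 to 1.57, Ptgs2 to 3.15 and Stmn1 to -1.89 with classes named within the set. Neutrophil markers were higher (9 of 10, 1.59). Of the healthy cells 420 of 777 came from a cluster with F13a1, Chil3, Ccr2 and Vcan among its top genes, which held 1327 of the 1497 day 30 cells. The other 357 and 170 came from a cluster with Ace, Treml4, Cd300e and Hpgd among its top genes. A shift between these clusters thus enters the ratios of Vcan, Chil3, Cd300e and Hpgd, to an extent that was not tested. Within-set naming kept only the latter cluster in the class, so the values given for it describe a different set of cells.

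The day 7 pair sets a tumour titled COX2-KO against a tumour titled WT, and whether the knockout lies in the tumour cells or the host is not given in the sources used here. Ptgs2 was detected in both libraries, with 42287 UMIs in the WT and 10103 in the COX2-KO library, and in macrophage-like cells its level was 1134 CPM (1115 to 1154) in WT and 692 (668 to 717) in COX2-KO (log2 ratio -0.71, -0.77 to -0.66). The ratio was -0.28 (-0.33 to -0.22) in neutrophil-like cells, at 3678 and 3034 CPM, -0.47 in monocyte-like cells, -1.25 (-1.35 to -1.15) in fibroblast-like cells, at 422 and 178 CPM, -0.37 (-0.81 to 0.05) in epithelial-like cells and -0.25 (-0.62 to 0.12) in T cell-like cells. Among the other classes, endothelial-like cells had 136 CPM (121 to 154) in WT and 12.7 (7.63 to 19.8) in COX2-KO, from 273 and 19 UMIs, and dendritic-like cells 177 (166 to 188) and 88.5 (78.1 to 99.8). These are 3' tags, and where they lie outside a deleted part, or the cells are not those that carry the deletion, they check nothing about the genotype. Macrophage-like cells held 16.0% (15.2 to 16.7) of the WT and 17.4% (16.2 to 18.7) of the COX2-KO library, neutrophil-like cells 26.6% (25.7 to 27.6) and 12.3% (11.3 to 13.5), T cell-like cells 9.98% and 13.7%, and fibroblast-like cells 6.39% and 8.90%. The macrophage-like shares, and all day 7 levels of that class, leave out unnamed clusters closest to macrophages. These held 817, 820 and 411 WT and 504, 349 and 158 COX2-KO cells, against 1455 and 597 named ones. The last of them was led by Cbr2 and Folr2, with Cd163 and Lyve1 among its top genes.

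Macrophage-like cells of the library labelled COX2-KO had less Il1b, at 2516 against 3391 CPM (-0.43, -0.46 to -0.40), less Il1a (-0.50) and less Spp1 (-0.95, -1.01 to -0.89), slightly more Cxcl2 (0.21) and Nlrp3 (0.15), and Il1rn (-0.02) and Tnf (-0.09, -0.25 to 0.06) within counting error. C1qa was at -0.20 and Folr2 at 0.90 (0.45 to 1.34). After thinning to 1500 UMIs, Il1b was detected in 82.7% of WT (80.6 to 84.7) and 72.6% of COX2-KO macrophage-like cells (68.7 to 76.2), with 55 and 35 shallower cells left out, and in 92.9% and 83.2% without thinning. In T cell-like cells, taken as background, the thinned shares were 9.20% and 5.05%, at median depths of 5178.5 and 9468.5 UMIs against 6539 and 6177. The lysozyme gene Lyz1 (3.63), Retnla (2.43), S100a4 (1.54), Ear2 (1.52), the heat shock gene Hspa1a (1.46) and the lipoprotein lipase gene Lpl (1.46) had the highest ratios, and Dnase1l3 (-1.43), the oxygen sensor gene Egln3 (-1.37), the chemokine gene Ccl3 (-1.26) and Mt2 (-1.12) the lowest. Of the Spp1 and hypoxia genes 10 of 12 were below WT (-0.46, percentile 0), whereas 10 of 14 TNF and IL-1 response genes were above it (0.38, percentile 99.98), with Lif at -1.50 and Saa3 at 0.81. Dissociation stress genes were above in 12 of 12 cases (0.52, percentile 100) and interferon response genes in 11 of 13 (0.23, percentile 99.0). Cytokine genes were split, 5 and 9 (-0.07, percentile 15.5), as were resident macrophage genes, 7 and 3 (0.06), with the scavenger receptor gene Cd163 at 2.43. Neutrophil granule genes were below in 5 of 5 (-1.18), with neutrophil markers at -1.45. The cluster led by Retnla, Ear2, Lpl and Lyz1 held 71 of 597 COX2-KO and 64 of 1455 WT cells, and with classes named within the set Lyz1 turned to -0.73 and Retnla to -1.36. At resolution 2 Folr2 (-0.01), Cd163 (-0.18) and Lif (0.02) turned as well.

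Monocyte-like cells differed in the same direction for Il1b (-0.83, -0.91 to -0.76), with Tnf at -1.26, Cxcl2 at -0.86 and 11 of 14 cytokine genes below WT (-0.79, percentile 0), while Spp1 was at 1.60 (1.34 to 1.87) and 11 of 13 interferon response genes were above (0.32, percentile 99.99). Dissociation stress genes were above in 9 of 12 cases there (0.52, percentile 100), with Hspa1a at 1.48 and Fosb at 1.45, and neutrophil markers below in 9 of 9 (-1.09). In neutrophil-like cells Il1b stood at 12813 against 16354.5 CPM (-0.35, -0.38 to -0.33), Nlrp3 at 0.46 and Il1rn at 0.23. There Edn1 (1.52) and Fosb (1.49) had the highest and Hspa1b (-2.60), Arg1 (-1.63) and Saa3 (-1.59) the lowest ratios. Spp1 and hypoxia genes were below in 9 of 12 cases (-0.30, percentile 0.02) and granule genes in 7 of 9 (-0.56, percentile 0.015), with the surface protein gene Cd177 at -1.19.

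Fibroblast-like cells of the library labelled COX2-KO had lower levels across inflammatory and contractile lists. Cytokine genes were below WT in 15 of 15 cases (-0.77, percentile 0), TNF and IL-1 response genes in 15 of 16 (-0.61, percentile 0) and myofibroblast genes in 8 of 10 (-1.20, percentile 0). Examples were Csf3 (-4.81), Csf2 (-2.53), Saa3 (-1.68, -1.71 to -1.65), Il6 (-1.15, -1.24 to -1.05), Acta2 (-1.89), Tagln (-1.69) and Lrrc15 (-1.47). Mmp13 (-3.08), Barx2 (-2.40), Serpinb2 (-2.34), Rnd1 (-2.31) and Nos2 (-2.15) had the lowest ratios. Cfd (9.69, 7.83 to 12.74, 2 UMIs in WT), Mup11 (at least 618-fold), Car3 (6.20) and Smpd3 (2.58) had the highest, though Cfd was at -0.12 with doublets kept. Ptges did not differ beyond counting error (0.01, -0.12 to 0.14), while Cxcl2 was at -1.08 and Il1b, at levels below those of T cell-like cells, at -1.43. Inflammatory fibroblast genes were below in 7 of 10 (-0.34), proliferation genes in 11 of 12 (-0.42), interferon response genes in 11 of 13 (-0.37) and Spp1 and hypoxia genes in 9 of 12 (-0.37), with neutrophil markers at -1.13. A cluster held 185 of 305 COX2-KO and 415 of 583 WT cells, another the rest.

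Epithelial-like cells, 65 in the COX2-KO and 178 in the WT library, had higher levels of Gpnmb (6.50), Sfrp1 (5.54) and the keratin genes Krt75 (5.89) and Krt17 (3.91) in the COX2-KO library, whereas Platr31 (at least 160.2-fold), Krt71 (at least 84.1-fold) and Krt25 (at least 65.2-fold) were higher in WT, with no UMI in the other. A cluster with Krt14, Krt5 and Krt17 among its top genes held 18 of the COX2-KO and 26 of the WT cells. The rest, 47 and 152, came from another, so the mix of clusters enters these ratios. Dissociation stress genes were above in 12 of 12 cases (1.08, percentile 100) and myofibroblast genes in 7 of 8 (1.97, percentile 100). T cell-like cells of that library had lower proliferation genes in 12 of 12 cases (-0.92, percentile 0), such as Ccnb1 (-1.41), and lower regulatory T cell genes in 6 of 6 (-0.59, percentile 0), such as Ikzf2 (-0.70) and Foxp3 (-0.59). Dissociation stress genes were above in 11 of 12 (0.76, percentile 100) in the same cells, with Hspa1a at 1.66 and Fosb at 1.48. The interleukin gene Il10 was at 1.74 and Slc12a2 at -2.06. MHC class II genes were above in 8 of 8 (1.35, percentile 100), as were 8 of 10 macrophage markers (0.86). Doublet removal took 3.88% of WT but 0.378% of COX2-KO barcodes, and with doublets kept the MHC class II list of these cells stood at 0.16 and the resident macrophage list at -0.34. The unnamed clusters held 22.6% of WT and 29.9% of COX2-KO cells.

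**Figure D5:**
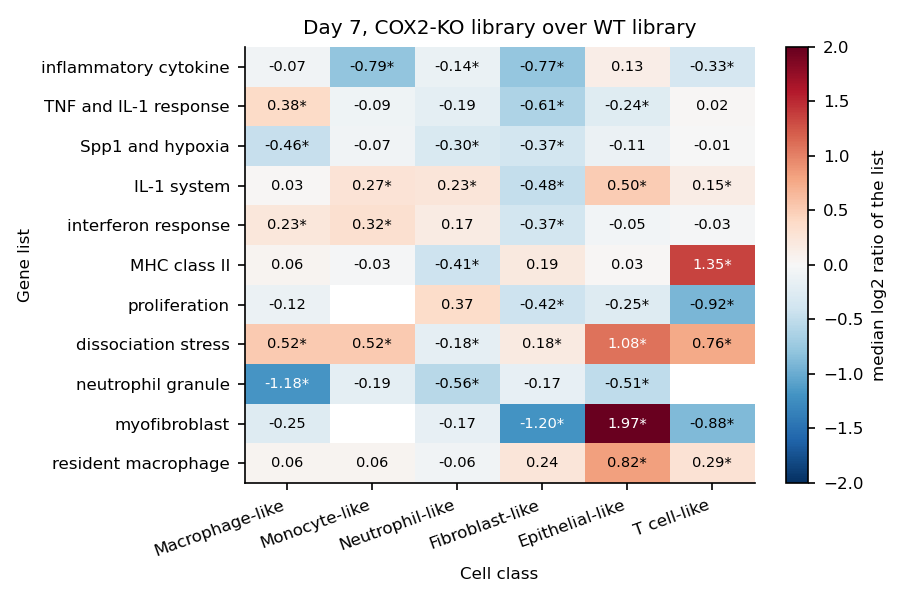
Median log2 ratio of the COX2-KO over the WT library on day 7 (colour and printed value) for fixed gene lists (y axis) in 6 cell classes (x axis), with 1 library per genotype label. Asterisks mark medians in the outer 2.5% at either end of 10000 random lists, blank fields have too few members, and the cytokine list stood at -0.77 in fibroblast-like and -0.07 in macrophage-like cells.

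The KC comparison asks whether the site of the tumour, in the pancreas or elsewhere, goes with a difference in its myeloid cells. In macrophage-like cells Il1b was at 6277 ± 1359 CPM in orthotopic and 3639.9 ± 1989 in heterotopic tumours (TMM-scaled, SD, n = 2 each; log2 fold change 0.79, SE 0.557, adjusted p = 0.702, edgeR with Benjamini-Hochberg adjustment), and Ptgs2 at 1916 ± 1193 and 982 ± 697 CPM (0.96, SE 0.634, adjusted p = 0.683), neither past the threshold. The same held for Nlrp3 (0.81, SE 0.467), C1qa (-0.92, SE 0.538), Spp1 (-0.61), Il1rn (-0.30), Il1a (-0.13), Tnf (-0.10) and Cxcl2 (-0.04). Of 7653 genes 3 rose and 3 fell, with 610 at an unadjusted p under 0.05. Among them, the nucleoside diphosphate kinase gene Nme2 (chromosome 11, 93949814 to 93956259) fell from 138 ± 59.9 to 11.9 ± 2.73 CPM between heterotopic and orthotopic libraries (-3.49, SE 0.495). Named after their values were seen were the gene model Gm43796 (-4.04), which fell, and Rpl7a-ps5 (3.34), Gm6576 (4.07) and Rpl13a-ps1 (3.16), which rose. Nme2 and the ribosomal protein pseudogenes Rpl7a-ps5 and Rpl13a-ps1 belong to families with closely similar copies, so their counts are uncertain. For the 6 genes adjusted p lay between 0.0421 and 0.0432 (edgeR, Benjamini-Hochberg). DESeq2 called 26 genes and edgeR without a low-count filter 90. No gene was called by edgeR with doublets kept, at resolutions 0.5 and 2 or with classes named against all sets, with 598, 602, 620 and 1173 at an unadjusted p under 0.05 in that order.

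By list, proliferation genes fell in macrophage-like cells of orthotopic tumours by camera (median -1.09, adjusted p = 0.000446, Benjamini-Hochberg), with the cell cycle kinase gene Cdk1 at -2.03 and 5 genes lower adjusted over the list alone against 0 over all genes. Resident macrophage genes (-1.04, adjusted p = 0.00372 by camera with Benjamini-Hochberg; Apoe -1.48, Pltp -1.40), MHC class II genes (-0.51, adjusted p = 0.0153; Cd74 -1.89) and T cell cytotoxicity genes (-0.52, adjusted p = 0.0324; Gzma -2.87) fell as well, and for all 4 the adjusted p was 0.763 with an estimated correlation. Adjusted over the list alone, 1 gene each was lower among T cell cytotoxicity, granule and monocyte identity genes. The other lists were not called, among them inflammatory cytokine (0.22, adjusted p = 0.526) and prostaglandin pathway genes (adjusted p = 0.938, camera with Benjamini-Hochberg). A cluster led by Ccl8, Apoe and C1q genes held 11 of 241 and 75 of 703 orthotopic but 264 of 450 and 51 of 84 heterotopic cells, and another held 204 of the cells of the first orthotopic library. An unnamed cluster led by the proliferation genes Pclaf, Stmn1 and Birc5, outside the class, held 1 and 101 orthotopic and 7 and 5 heterotopic cells. Signs of median and test differed for Spp1 and hypoxia (0.03), TNF and IL-1 response (-0.01) and inflammatory fibroblast genes (-0.70).

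In neutrophil-like cells no gene of 4127 passed edgeR's threshold, with 180 at an unadjusted p under 0.05, 15 called by DESeq2 and 106 without a low-count filter. Il1b was at 10571 ± 4273 and 9722 ± 6726 CPM (0.12, SE 0.914, adjusted p = 0.999, edgeR with Benjamini-Hochberg). Granule genes had positive values in 10 of 10 cases, with Ngp at 9263 ± 12576 against 10.6 ± 2.64 CPM (9.83, SE 1.95), Camp at 9.55 and Ltf at 5.79, and 7 were higher adjusted over the list alone, as was 1 monocyte identity and 1 inflammatory fibroblast gene. Camera called that list (3.02, adjusted p = 3.46e-14, Benjamini-Hochberg) and TNF and IL-1 response genes (0.57, adjusted p = 0.0324; Lcn2 3.10, Il6 2.97) upward, and MHC class II (-1.46, adjusted p = 1.05e-05; Cd74 -2.89), resident macrophage (-1.53, adjusted p = 1.59e-05) and Spp1 and hypoxia genes (-0.62, adjusted p = 0.0324; Arg1 -2.32) downward. With an estimated correlation the adjusted p was 0.763 for the first 4 and 0.865 for the last, and the median (0.07) and test of the cytokine list differed in sign. Macrophage markers were negative in 10 of 10 cases (-1.49). The libraries drew on different clusters, and a cluster led by Camp, Ngp and Ltf held 52 of the 106 cells of the second orthotopic library, 5 of 230 in the first, and 0 of 126 and 8 of 705 in the heterotopic ones. Of the cells of the first orthotopic library 218 came from a further cluster, and 116 and 696 of the heterotopic cells from another.

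Shares varied widely between libraries of a group. Macrophage-like cells held 39.1% ± 4.03 of orthotopic and 37.6% ± 40.2 of heterotopic cells (exact two-sided permutation test, p = 1), neutrophil-like cells 22.8% ± 24.5 and 47.6% ± 41.2 (p = 0.667, exact permutation) and dendritic-like cells 3.33% ± 1.501 and 1.66% ± 0.347 (p = 0.333, exact permutation), where 0.333 is the smallest p that 2 libraries against 2 allow. Gene counts in macrophage-like cells moved with single libraries, to 142 and 423 without the first and second orthotopic and 25 and 5 without the first and second heterotopic library. Of the 6 genes called with all libraries, 6 were called without either orthotopic library, 3 without the first and 2 without the second heterotopic library. In neutrophil-like cells, where none had been called, leaving out a library gave between 29 and 105 genes.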

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

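The tests of the low-depth library, of the splits, of free RNA in neutrophil-like cells of tumours and of a shift between fibroblast-like clusters were chosen only after the results had been seen.

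The GEMM libraries, which entered no comparison between groups, had signals in macrophage-like cells above the level of healthy pancreas. In the first, Il1b stood at 168.7 CPM (95% interval 156 to 182) against 93.3 (74.3 to 116), Il1rn at 43.5 against 23.6, Nlrp3 at 45.3 against 22.5 and Cxcl2 at 893 against 41.6. Both GEMM libraries exceeded the healthy level for Ptgs2, at 20.6 and 23.9 CPM against 2.25, Tnf, at 30.7 and 25.5 against 5.62, and Spp1, at 42.7 and 217 against 12.4, and the second did for Il1rn, at 102.04. The second library had Il1b at 114 CPM (99.5 to 131), Nlrp3 at 29.2 (22.02 to 38.05) and Cxcl2 at 43.05 (34.2 to 53.5), whose intervals overlap those of healthy pancreas. The levels come from different sets with different gene tables, so they are set side by side only, and the intervals cover counting error only. They leave out a cluster led by Retnla and Lyz1, closest to macrophages but unnamed, with 359 and 90 cells against 238 and 176 named ones, and unnamed cells held 58.7% of the Ptgs2 UMIs of the first library.

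In macrophage-like cells of KC tumours, the 6 genes called between sites included Nme2, a pair of ribosomal protein pseudogenes and a pair of unnamed gene models. The depth of the first orthotopic library is argued against as the whole cause, since 6 of the 6 were still called without it. Reads assigned differently among near-identical gene copies in the libraries of each site may account for the pattern: 6 of the 6 differed the same way, by at least 50% of their log2 change, in all cells outside the class. There the log2 ratios ran from -4.18 for Gm43796 to 5.60 for Gm6576. A difference of tumour site that acts on all cells alike stays open and was not tested.

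Neutrophil-like cells of tumours and blood differed in 6453 genes, and the highest count among the other 9 splits of the 6 libraries was 0. With 1 of 10 splits reaching the real count, the splits are too few for a share under 0.05. Free RNA of other tumour cells is argued against for the inflammatory cytokine list, of which 14 of 14 members that rose lay above the rest of the cells in every tumour library. For resident macrophage, MHC class II, epithelial, acinar and fibroblast genes it could account for the rise, since 0 of 40 lay above the rest. Tissue and its dissociation cannot be told apart by these libraries, and a response of neutrophils to the tumour stays open and was not tested.

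Genes that respond to TNF or IL-1 were lower in fibroblast-like cells of the library labelled COX2-KO, with a median log2 ratio of -0.61. Less free RNA from its smaller share of neutrophils is argued against, because the 8 members at a higher level in fibroblast-like cells than in the rest of both libraries had a median of -0.73. A shift in shares between the fibroblast-like clusters is argued against as the whole cause by a median of -1.11 within the cluster of 185 COX2-KO and 415 WT cells. In the other, with 120 and 168 cells, the median was 0.0369, so the bound set beforehand, a difference within each cluster, was not met. The genotype named in the title, in host or tumour cells, stays open and untested as a biological explanation, as does any other difference between these single libraries.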

How the results depend on the processing

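Tests with the classes named against all sets or within the set, fry and calls above the rest of the cells were chosen only after the results had been seen. Where a group has 1 library, nothing shows how much pools of mice vary. Where leaving out a KC library left a single one at a site, that library was assumed to vary like the others. The KC libraries hold at most 703 macrophage-like cells each, and with 2 libraries per site edgeR recovered none of the 2-fold changes in simulated data and DESeq2 1 of 67 in each class. Classes named within the set gave no value for KC macrophage-like cells. All other alternatives listed before the data were examined were run, and unless a reason is given, the cause was not tested.

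Among the values that lead a comparison, 79 stayed within their error or within 1.5 times under an alternative and 88 did not. Of the other values, 4116 stayed the same, 737 moved by more than their error without changing sign, 37 lost their call, 41 gained one and 27 reversed. No value reversed or moved beyond these bounds with DESeq2 size factors or, in tumour against blood, without the day term or without the libraries of any day, where gene counts ran from 5074 to 7759 against 6453.

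The number of genes called between KC sites in macrophage-like cells (6) was 26 with DESeq2, 90 without a low-count filter, 3 with the stricter cell filter, 0 with doublets kept, at resolutions 0.5 and 2 and with classes named against all sets, and from 5 to 423 without a library. In neutrophil-like cells (0) it was 15 with DESeq2, 106 without a low-count filter and from 29 to 105 without a library. Lists called went to 0 with an estimated correlation in all 3 comparisons and to 0 with fry in both KC classes. Tumour against blood kept 2365 genes when only calls above the rest of the cells were counted, which removes genes by construction. With the replicate number as a block, KC macrophage-like cells gave 239 genes and 5 lists and neutrophil-like cells 18 genes and 7 lists, against 4 and 5 lists without it. The deviations of same-numbered KC libraries correlated at 0.161 and 0.0211 over 2 pairs, which share only a number.

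Shares moved as follows. The macrophage-like share of day 10 (33.4%) was 29.3% with the stricter filter, 22.3% at resolution 2, 22.1% with classes named against all sets and 21.8% within the set, and that of day 30 (23.3%) was 32.7% with the stricter filter, 22.6% with doublets kept, 28.2% and 28.1% at resolutions 0.5 and 2 and 28.5% named against all sets. The neutrophil-like share of healthy blood (10.8%) was 8.43% at resolution 2 and 8.28% named against all sets, that of day 30 blood (39.1%) 34.7% with the stricter filter, 31.7% at resolution 2 and 31.2% named against all sets, and that of the day 7 WT tumour (26.6%) 24.0% with the stricter filter.

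The log2 ratio of Il1b in macrophage-like cells between day 30 and healthy pancreas (5.90) was 5.46 with the stricter filter, 5.54 at resolution 2, and 5.51 and 5.57 with classes named against all sets and within the set. Between days 30 and 10 (1.24) it was 1.18 with median ratio scaling, 1.22 with the stricter filter, 1.22 and 1.19 at resolutions 0.5 and 2, and 1.16 and 1.22 with the other names. On day 7 (-0.43) it was -0.46 with median ratio scaling, -0.50 with the stricter filter, -0.27 and -0.53 at resolutions 0.5 and 2, and -0.66 and -0.29 with the other names, and in neutrophil-like cells (-0.35) -0.31 with median ratio scaling.

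The share of macrophage-like cells with Il1b followed the depth of thinning by construction, with 67.2% and 85.3% on day 10, 87.8% and 95.6% on day 30, 76.3% and 88.96% in the day 7 WT and 62.6% and 80.2% in the COX2-KO tumour at 1000 and 3000 UMIs, and 14.1% in healthy pancreas at 3000. With the stricter filter it was 90.7% on day 30, 12.2% in healthy pancreas and 67.3% in COX2-KO, and at resolution 2 90.7% on day 30, 71.9% in WT and 59.2% in COX2-KO. It was 76.96% in COX2-KO at resolution 0.5, 89.6%, 74.1% and 58.4% on day 30, in WT and in COX2-KO named against all sets, and 15.3% in healthy pancreas and 77.6% in COX2-KO named within the set. Cytokine genes positive with Il1b in every library (2) numbered 4 at 3000 UMIs, 1 with the stricter filter, 7 with doublets kept, 6 at resolutions 0.5 and 2 and 5 named within the set. Resident genes negative in all (5) were 2 with the stricter filter, 8 and 9 at resolutions 0.5 and 2, and 3 and 1 named against all sets and within the set. Some signs follow the Il1b share alone, so these counts do not measure co-detection. At resolution 0.5 8 libraries had enough cells, and at resolution 2 and within the set 9, so "every library" was easier to meet.

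Reversed values, as log2, were these. With classes named within the set, Camp (2.86) and Ngp (2.89) in tumour against blood, Nlrp3 (-0.0855), Cxcl2 (-0.17) and the cytokine list (-0.0290) in neutrophil-like cells between days 30 and 10, Ptgs2 (3.15), Ifit3 (0.61), Cxcl10 (1.57), Stmn1 (-1.89) and the interferon list (0.24) in day 30 blood monocyte-like cells, and Lyz1 (-0.73) and Retnla (-1.36) in day 7 macrophage-like cells turned. At resolution 0.5 Lyz1 (-1.30) and Retnla (-1.35) did too, as did the IL-1 system list in monocyte-like (-0.0425) and T cell-like cells (-0.10) and the resident macrophage list in T cell-like cells (-0.14). At resolution 2 Folr2 (-0.0116), Cd163 (-0.18) and Lif (0.0221) turned in day 7 macrophage-like cells and the IL-1 system list (-0.14) in T cell-like cells. With the stricter filter Folr2 (-0.18) turned there. With doublets kept, H2-Ab1 (-0.68) turned in tumour against blood, Cfd (-0.12) in day 7 fibroblast-like cells, and the resident macrophage (-0.34) and IL-1 system lists (-0.73) in day 7 T cell-like cells. With median ratio scaling Il1b (0.0495) turned in blood neutrophil-like cells.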

Other observations

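None of the values here was tested, and all were chosen after the data had been seen.

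Genes of prostaglandin E2 synthesis and of prostaglandin E2 and IL-1 receptors differed between cell classes of the pancreas and its tumours. Il1r1 was highest in fibroblast-like cells of the time course tumours, at 165 (95% interval 154 to 176), 109.8 and 193 CPM on days 10, 20 and 30. It stood at 28.9 in those of healthy pancreas and at most 3.13 in tumour macrophage-like cells. Day 20 fibroblast-like values here include the cluster scored near epithelial. Endothelial-like cells had 67.0, 37.0 and 23.7 CPM. Ptges was likewise highest in fibroblast-like cells, at 105, 69.6 and 83.2 CPM. Epithelial-like cells had 35.7 and 30.1 on days 20 and 30. Being more numerous, they held 77.5% and 65.6% of Ptges UMIs, against 18.7% and 28.1% in fibroblast-like cells. The Ptges level in macrophage-like cells was at most 7.40 CPM, although these cells held 51.3% of the Ptgs2 UMIs of the day 30 tumour. Ptger4, a receptor of prostaglandin E2, stood at 152, 232 and 189 CPM in dendritic-like cells against 48.4 in healthy pancreas, and at 51.4, 63.1 and 61.1 against 22.3 in T cell-like cells. Ptger2, another such receptor, stood at 15.1, 10.8 (6 UMIs) and 17.9 CPM in T cell-like cells against 2.84, and at 6.14, 11.3 and 15.03 in fibroblast-like cells against 3.50, which held 60.2% and 49.9% of its UMIs on days 20 and 30. On day 7 Il1r1 stood at 180.2 CPM in WT and 128 in COX2-KO fibroblast-like cells, and at 179.6 and 219 in the 43 and 23 pericyte-like cells, and Ptges at 120.6 and 122.

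The GEMM libraries were made up mainly of lymphocytes. T cell-like cells held 68.8% of the first and 19.8% of the second, B cell-like cells 16.3% and 54.3%, plasma cell-like cells 1.89% and 6.52%, of which 109 of 154 and 166 of 295 cells came from a cluster led by cell cycle genes such as Mki67 and Top2a, and macrophage-like cells 2.91% and 3.89%, against 44.4% T cell-like and 33.8% B cell-like cells in healthy pancreas. Epithelial-like cells held 0.171% and 1.04%. Unnamed cells held 4.43% and 2.65%, mostly a cluster led by Retnla and Lyz1 that the macrophage-like shares leave out. After thinning to 1500 UMIs, Il1b was detected in 16.0% (11.6 to 21.3) and 14.3% (9.46 to 20.4) of their macrophage-like cells, and in 38.7% and 27.8% without thinning. In T cell-like cells, taken as background, the thinned shares were 0.0910% and 0.235%, at median depths of 6311 and 4670.5 UMIs against 13757.5 and 9820.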
